A study of Homo sapiens with 8 samples.

How the data were processed

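Open chromatin was measured by ATAC-seq, in which the transposase Tn5 inserts sequencing adapters into accessible DNA, in A2780, an established human ovarian cancer cell line, and in 3 drug-resistant derivatives of it. Per the labels' protocols, nuclei were treated with Tn5 and libraries were barcoded with Nextera indices and amplified by PCR. The 4 groups were control cells, cisplatin-resistant cells, paclitaxel-resistant cells and cells resistant to both drugs (called dual-resistant here), with 2 libraries each and 8 in all. Whether drug was present when the cells were collected is not given in the sources used here. Nothing in the labels says that the 2 libraries of a group came from separate cultures. The p-values therefore measure only the spread between libraries of a group, taken largely over all peaks, and that spread may be technical.

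The deposited matrix holds CPM values for 159451 consensus peaks of 1001 bp each, per the file headers and the values. Reads were scaled so that the peaks of each library sum to a common total, so a gain or loss shared by all peaks cannot be seen. Each library was matched to its column through the column name that its label gives. No column was left unmatched. Bowtie2, Picard and MACS2 are named in the submitters' processing notes together with the build hg38. Their versions, roles and settings, the treatment of reads that map to several places, any shift of reads for the Tn5 cut site, and the way peaks of the libraries were merged are not given in the sources used here. Each consensus peak carries the name of 1 peak of 1 library, which is taken up among the results for a closer look.

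The CPM values were whole multiples of a fixed step in each library, and dividing by the step gave whole reads within 0.01 read for 100% of the values. Recovered reads in peaks were 7693492 and 7769112 in control, 8885297 and 8552256 in cisplatin-resistant, 8236447 and 8898337 in paclitaxel-resistant and 8087535 and 9304798 in dual-resistant libraries 1 and 2. One read was therefore worth 0.107 to 0.130 CPM, and a count of 0 allows a level of up to 0.322 to 0.390 CPM (3 reads per library). These floors cover counting error only, because PCR reads without molecular identifiers are not independent molecules. Between the 2 libraries of a group the chi-square per degree of freedom was 1.88 in control, 2.14 in cisplatin-resistant, 2.02 in paclitaxel-resistant and 2.22 in dual-resistant cells over peaks with at least 20 reads. PCR reads alone can bring such a ratio above 1, so it does not show how the libraries of a group were made, and each was counted as a library because the labels list it as a sample.

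The following choices were made before the data were examined. Peaks with at least 1 CPM in at least 2 libraries were tested, which kept 158698 peaks. Values were taken as log2(CPM + 0.5), and limma (version 3.58.1, R 4.3.3) was fitted to all 4 groups together, with group as the only term and a variance trend (4 residual and 98.5 prior degrees of freedom). With these degrees of freedom the SE of a peak came mostly from the trend over all peaks and little from its own libraries. An SE can thus be small where the 2 libraries of a group differ widely, and very small p-values rest on this pooling. Each resistant line was compared with control, the resistant lines were compared with each other, and an interaction term tested whether the dual-resistant line departed from the sum of the log2 differences of the single-resistant lines. A peak was called at a Benjamini-Hochberg adjusted p under 0.05 over all tested peaks. Log2 differences are on the log2(CPM + 0.5) scale and understate the change of weak peaks.

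Peaks were placed on genes with a RefSeq table of gene spans for GRCh38, the same build as hg38. That table gave no strand and no exons, so the planned promoter window of 1 kb around a transcription start could not be used. A gene was represented instead by its gene-end peak, the tested peak with the highest mean CPM within 1 kb of either end of its span, and 15952 of 19974 protein-coding genes had one. Which end holds the start, and whether a peak lies in an exon, an intron or an untranslated region, was not resolved. A peak further away but within 100 kb was assigned to the nearest protein-coding gene as a distal peak. Planned motif sets were not run because no genome sequence was used here.

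For each comparison with control, the named genes were chosen by a fixed rule. It took the 8 higher and 8 lower called gene-end peaks of protein-coding genes with the largest absolute log2 difference, where the libraries of the groups did not overlap and the higher group averaged at least 3 CPM. It also took up to 4 called members of each gene list with an absolute log2 difference of at least 1, by smallest p, and the 3 genes per direction with the most called distal peaks. ABCB1, ABCG2, ABCC2, ATP7B, SLC31A1, TUBB3, GSTP1, CDKN1A and ALDH1A1 were always included where measured, with their strongest peak over the gene as well. Among resistant lines the rule took 5 and 5 gene ends and the same fixed genes. The text prints part of the genes the rule named. Gene ends that differed from control in all 3 resistant lines are also given as examples, and these need not be in the rule. Elsewhere the text says so where a peak outside the rule is given. A few genes that the rule named are not reported here.

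The 26 gene lists held 719 genes, all of which matched the reference. They were AP-1 and immediate early genes, mesenchymal genes, epithelial genes, TGF-beta and BMP signalling, NF-kB and inflammatory genes, interferon-stimulated genes, WNT signalling, NOTCH signalling, receptor tyrosine kinases and ligands, HOX genes, stem cell associated genes, cancer-testis antigens, p53 targets, apoptosis regulators, cell cycle genes, mismatch repair, nucleotide excision, crosslink and homologous repair, glutathione, metallothionein and NRF2 targets, drug efflux and uptake transporters, cytochrome P450 and aldo-keto drug metabolism, tubulins and microtubule regulators, neighbours of ABCB1, housekeeping controls, and markers of fibroblast, endothelial and haematopoietic cells. Lists were tested with camera at a preset correlation of 0.01, adjusted over the 26 lists of a comparison, and again with an estimated correlation.

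Regional shifts were measured as the median log2 difference from control of tested peaks in bins of 5 Mb with at least 20 peaks, and a bin was called shifted when the median was at least 0.5 from 0 in both libraries. Overlaps between comparisons were set beside independent lists and beside 20 simulated runs of unchanged groups that shared simulated control libraries. In simulated data 50 peaks per fold size were changed, all drawn from peaks with a control mean of at least 2 CPM. The test recovered every peak raised 4-fold and 54%, 54% and 58% of those raised 2-fold in the cisplatin, paclitaxel and dual designs. Of peaks lowered to 0.25 of their level it recovered 88%, 90% and 88%, and of those lowered to 0.5 of it 38%, 50% and 40%. It called 9, 11 and 13 unchanged peaks in those designs, of 143675, 143692 and 143653 tested, and gave no change in the wrong direction. Only 200 peaks were changed per design, far fewer than the data called, and weaker peaks were not tried. These rates therefore need not carry over to the data.

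Other settings fixed beforehand were pseudocounts of 0.1 and 2, no filter and a filter of 3 CPM, quantile, median-ratio and cyclic loess scaling, the replicate number as a block, fits of the compared groups alone, a robust fit, a log2 minimum of 1, subtraction of regional medians, each library left out in turn, a gene-end window of 2.5 kb, the mean of all gene-end peaks, and bins of 10 Mb. Settings chosen after seeing the data were the edgeR (version 4.0.16) quasi-likelihood test on recovered reads, subtraction of chromosome medians, a fit without the cisplatin-resistant group, and list tests on the strongest peak over each gene. Files were read with the data.table package, version 1.17.8, and drawn with Python 3.11.15 and matplotlib 3.10.9.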

Results

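The accessible chromatin of A2780 ovarian cancer cells was compared between drug-sensitive control cells and derivatives resistant to cisplatin, a platinum drug that crosslinks DNA, to paclitaxel, a drug that stabilises microtubules, or to both. Each group had 2 libraries, with 7693492 to 9304798 reads in peaks per library. The 1% of peaks with the most reads in a library held 15.0% and 14.9% of reads in peaks in control libraries. This share was 13.7% and 13.9% in cisplatin-, 16.4% and 16.3% in paclitaxel- and 13.1% and 12.8% in dual-resistant libraries. Whether it sets the balance of higher and lower gene ends was not tested. Levels are given as mean ± SD in CPM with n = 2 libraries, and differences as log2 values with limma's standard error (SE) and Benjamini-Hochberg adjusted p. Coordinates are on hg38. Across peaks, which are not independent replicates, libraries of the same group correlated at 0.926 to 0.933 on the log2 scale. Control libraries correlated with paclitaxel-resistant libraries at 0.807 to 0.808, with dual-resistant libraries at 0.816 to 0.826 and with cisplatin-resistant libraries at 0.658 to 0.671. The first principal component, with 49.7% of the variance, set the cisplatin-resistant libraries (scores 327 and 319) apart from the other 6 (-48.6 to -144).

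The first question was which gene ends differed from control in all 3 resistant lines. The genes printed for it are examples and need not follow the fixed rule. ULBP1, which encodes a stress-induced ligand of the immune receptor NKG2D, rose from 0.259 CPM to 8.93, 39.4 and 17.3 CPM in cisplatin-, paclitaxel- and dual-resistant cells (6:149963226-149964226). FUT4, a fucosyltransferase gene, rose from 0.453 CPM to 13.4 CPM or more in each line (11:94543660-94544660). PHF11, a PHD finger gene, rose from 1.55 CPM to 17.1, 25.2 and 16 CPM (13:49495265-49496265). The largest adjusted p over the 3 lines was 1.26e-26 for ULBP1, 1.32e-29 for FUT4 and 4.62e-24 for PHF11.

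Among gene ends that fell in all 3 lines, ESRRG, an orphan nuclear receptor gene, went from 14.9 CPM to 0.520, 1.22 and 0.610 CPM in cisplatin-, paclitaxel- and dual-resistant cells (log2 differences -3.92, -3.14 and -3.94). SIX6, a homeobox gene, went from 19.2 CPM to 3.27, 3.74 and 3.79 CPM (-2.39, -2.22 and -2.22). NOX4, which encodes an enzyme that makes reactive oxygen species, stood at 25.4 CPM in control cells and at 8.25, 0.818 and 0.322 CPM in the resistant lines. The neuronal kinesin gene KIF1A fell from 22.6 to 2.17, 5.30 and 5.28 CPM, the neurotrophin gene BDNF from 7.82 to 2.14, 0.537 and 1.12 CPM, and the VEGF receptor gene KDR from 10.6 to 3.08, 1.57 and 2.84 CPM. In total, 147 gene ends were higher and 341 lower than control in all 3 lines, as were 1053 and 1987 peaks of any location.

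**Figure D1:**
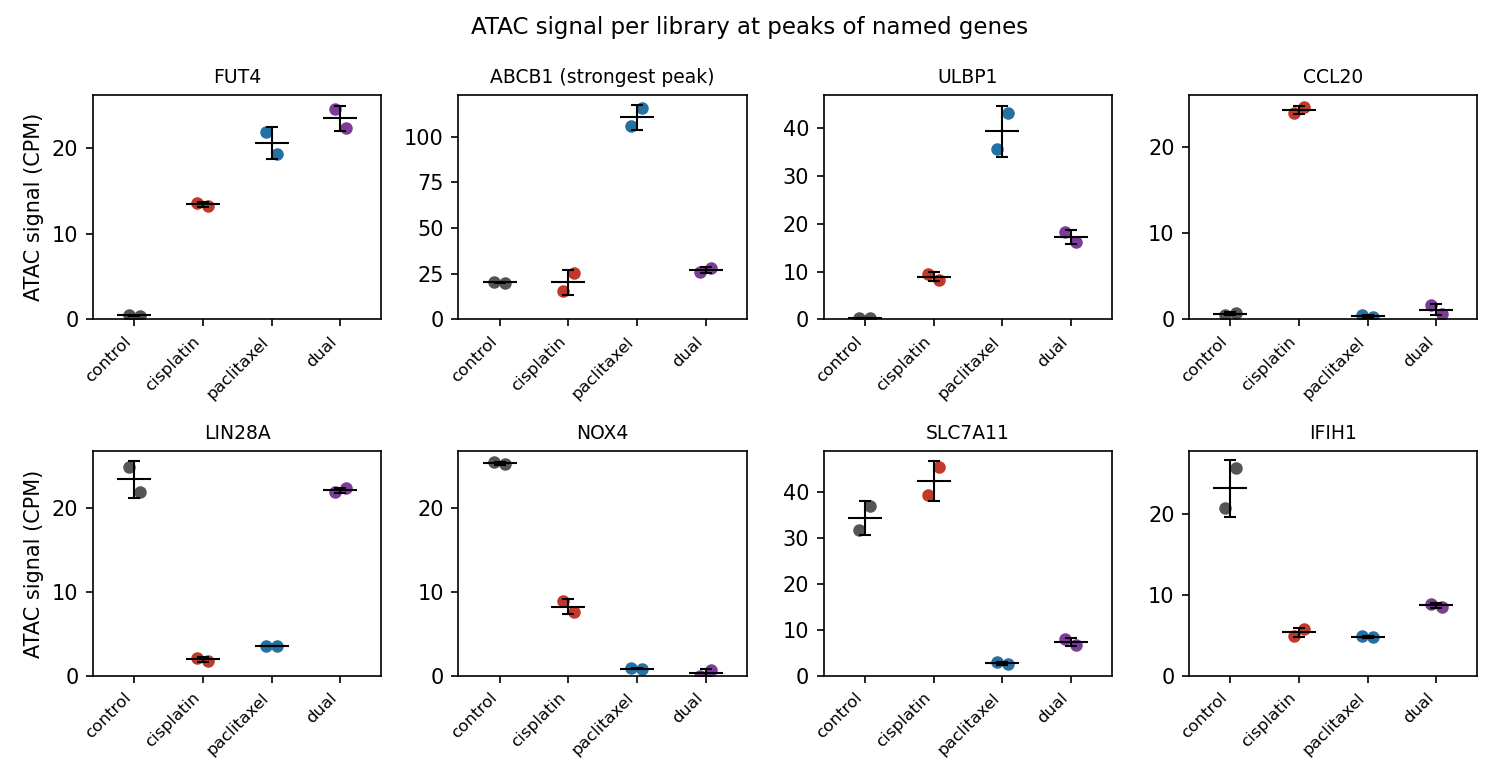
Levels in CPM (y axis) of the gene-end peaks of FUT4, ULBP1, CCL20, LIN28A, NOX4, SLC7A11 and IFIH1 and of the strongest peak over ABCB1 in the 4 groups (x axis), with points for single libraries and lines with bars for mean ± SD (n = 2). ULBP1 stood at 0.259 CPM in control and at 8.93 to 39.4 CPM in the resistant lines. The strongest peak over ABCB1, which is also the gene-end peak of RUNDC3B, reached 111 CPM in paclitaxel-resistant cells against 20.2 CPM in control.

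In cisplatin-resistant cells against control, the gene end of the chemokine gene CCL20 (2:227817853-227818853) rose from 0.646 ± 0.178 to 24.3 ± 0.495 CPM (log2 difference 4.45, SE 0.41, adjusted p = 2.15e-16). LY6K, a cancer-testis antigen gene (8:142699373-142700373), rose from 0.517 ± 0.179 to 29.0 ± 0.19 CPM (4.87, SE 0.40, adjusted p = 4.82e-19). The zinc finger gene ZNF582 (19:56383751-56384751) had no reads in control and 14.5 ± 1.2 CPM in the resistant cells, at least 37.3-fold higher against the floor of 3 reads per library. The developmental genes LIN28A, PAX2 and TLX3 fell. LIN28A, which encodes an RNA-binding protein of pluripotent cells, went from 23.4 ± 2.17 to 1.95 ± 0.272 CPM (1:26409175-26410175; -3.29, SE 0.23, adjusted p = 5.74e-24). The transcription factor genes TLX3 (28.3 ± 2.37 to 2.52 ± 0.0682 CPM) and PAX2 (12 ± 1.29 to 0.628 ± 0.226 CPM) changed by -3.25 and -3.48. UNC13C, a gene of synaptic vesicle priming, changed by -4.33 (30.5 ± 0.851 to 1.08 ± 0.538 CPM; adjusted p = 3.37e-24). At PAX2, 63 of 80 distal peaks within 100 kb were lower and 2 higher.

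Over all protein-coding gene ends, 1775 of 15952 were higher and 4555 lower in this comparison. Of 18 housekeeping controls, 2 were higher and 9 lower, so the list counts below are to be read beside a general lean to lower gene ends. By list, 7 of 23 AP-1 and immediate early genes rose and 2 fell (7 and 3 adjusted over the list alone). JUN, which encodes a subunit of the AP-1 transcription factor, rose from 21.6 ± 2.34 to 58.3 ± 0.276 CPM (1.41, SE 0.13, adjusted p = 7.82e-17), and 10 of its 12 distal peaks were higher. After regional medians were subtracted, 7 of these distal peaks were higher and 1 lower, and their median log2 difference went from 2.41 to 1.59. BATF3, whose product pairs with JUN proteins, fell from 25.5 ± 0.829 to 9.15 ± 1.86 CPM (-1.45). Of 38 interferon-stimulated genes, 17 fell and 5 rose (18 and 5 adjusted over the list alone). The cytosolic RNA sensor gene IFIH1, whose end is shared with GCA, fell from 23.1 ± 3.5 to 5.34 ± 0.55 CPM (-2.01, SE 0.22, adjusted p = 5.24e-13). The interferon regulatory factor genes IRF9 (-1.11) and IRF1 (-1.01) fell as well. In TGF-beta and BMP signalling 14 of 28 genes fell and 1 rose (16 and 1 adjusted over the list alone), among them BMP7 (-1.48) and INHBA (-1.22). Of receptor tyrosine kinases and ligands, 16 of 41 fell and 4 rose (17 and 4 adjusted over the list alone), with PDGFRB higher (2.23, 26.1 ± 0.299 against 5.18 ± 0.585 CPM) and NTRK2 lower (-2.31). NF-kB and inflammatory genes had 6 of 22 higher and 2 lower (6 and 2 adjusted over the list alone), with TRAF1 at 1.78 and BIRC3 at 1.15. With loess scaling the TGF-beta list had 7 lower and 4 higher and the receptor list 8 lower and 5 higher. The median of the NF-kB list was -0.07 although the mean and the test pointed up.

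Mesenchymal genes had 9 of 32 higher and 6 lower. Stem cell associated genes had 6 of 22 higher and 10 lower, and both pairs of counts were the same adjusted over the list alone. Loess scaling gave 5 higher and 5 lower for the stem cell list. Of markers of other cell types, 4 of 13 fibroblast genes were higher and 3 lower, 4 of 16 haematopoietic genes higher and 3 lower, and 1 of 8 endothelial genes higher and 2 lower (4 and 3, 4 and 4, and 1 and 3 adjusted over the list alone). ROBO4 (10.8 ± 0.0495 against 1.42 CPM), an endothelial guidance receptor gene, and CSF1R (7.35 ± 0.685 against 0.969 CPM), the macrophage growth factor receptor gene, were among the higher ones. Among the fixed genes, the strongest peak over ABCG2, a drug efflux transporter gene, fell from 19.9 ± 2.61 to 8.43 ± 0.178 CPM (4:88158615-88159615; -1.19, SE 0.20, adjusted p = 4.96e-07). The gene end of TUBB3, a beta-tubulin gene, rose from 15.6 ± 0.715 to 25 ± 2.46 CPM (0.66, adjusted p = 0.000333). Its strongest peak (16:89925883-89926883) fell from 28.3 ± 4.95 to 20.1 ± 2.3 CPM (-0.48, adjusted p = 0.00598), with no call without control library 1 (-0.30), without cisplatin-resistant library 2 (-0.37), with quantile (-0.35) or loess scaling (-0.29), or after regional (-0.32) or chromosome subtraction (-0.29). No call was made for the copper transporter genes ATP7B (-0.14, adjusted p = 0.329) and SLC31A1 (-0.12, adjusted p = 0.395), or for the glutathione transferase gene GSTP1 (-0.17, adjusted p = 0.397). The strongest peak over ABCB1, which is also the gene-end peak of RUNDC3B, was not called either (20.3 ± 6.87 against 20.2 ± 0.14 CPM).

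Over all peaks, 52757 of 158698 were called by limma, 29093 higher and 23664 lower, and 38252 of them differed by at least 2-fold. The 55.1% share of higher peaks became 47.9% with quantile scaling (27158 higher, 29533 lower) and 64.0% with median-ratio scaling (31889 higher, 17927 lower). Without control library 2 the lower count was 15717. Peaks at gene ends were called in 32.6% (2949 higher, 5873 lower), peaks inside genes in 31.6% (13804 higher, 8405 lower) and peaks outside genes in 35.4% (12340 higher, 9386 lower). Distal peaks were mostly higher around SMURF2 (41 of 52), FANCC (40 of 59) and CUBN (36 of 52), and mostly lower around DLG1 (64 of 95), PAX2 and ARMC9 (50 of 63). After the median of each 5 Mb region was subtracted, 24 were higher around SMURF2, and 42 lower around DLG1 and 33 around ARMC9. The DLG1 gene end, not called at -0.17, then stood at 0.26. MYC, the growth regulator gene (8:127735501-127736501), rose from 41.2 ± 4.77 to 85.5 ± 5.48 CPM (1.05), and the difference was -0.15 after the median of its 5 Mb region was subtracted. By camera none of the 26 lists was called (smallest adjusted p = 0.134 for AP-1 and immediate early genes, 0 with an estimated correlation, 6 lists at an unadjusted p under 0.05). After regional subtraction the AP-1 (up) and interferon (down) lists were called at adjusted p = 0.0397. Camera sets a list against all gene ends, whose median was -0.19 here, 0.01 in paclitaxel-resistant and -0.13 in dual-resistant cells. The median or mean had another sign than the test for 16, 4 and 7 of the 26 lists in these comparisons, and 0 of those lists were called.

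In paclitaxel-resistant cells against control, the region of ABCB1, the gene of the drug efflux pump P-glycoprotein, stood out. Its strongest peak, which is also the gene-end peak of RUNDC3B (7:87627559-87628559), rose from 20.2 ± 0.14 to 111 ± 6.91 CPM (log2 difference 2.43, SE 0.13, adjusted p = 1.93e-31), and 16 of 19 distal peaks of ABCB1 were higher. The gene-end peak of ABCB1 itself (7:87501517-87502517) rose from 1.10 ± 0.633 to 5.14 ± 0.116 CPM (1.88, SE 0.41, adjusted p = 0.000228). That of ABCB4, a phospholipid transporter gene beside it, rose from 2.59 ± 0.75 to 9.67 ± 0.792 CPM (1.74), and the end shared by CROT and TP53TG1 from 51.7 ± 1.36 to 151 ± 0.0515 CPM (1.53). Of the 13 listed neighbours of ABCB1, 8 rose and 0 fell (9 and 0 adjusted over the list alone; camera adjusted p = 2.62e-09, adjusted p = 0.155 with an estimated correlation). The largest difference in the region was at a peak inside ABCB4 (7:87448127-87449127), chosen after its values were seen, which went from 0.905 ± 0.177 to 115 ± 4.78 CPM (6.36, SE 0.23, adjusted p = 1.02e-44). After regional subtraction the strongest ABCB1 peak stayed higher (1.08), while 1 of the 19 distal peaks was called. The calls at the ABCB1 end (0.53), the ABCB4 end (0.39) and CROT (0.19) were lost and the median of the 13 neighbours went from 0.67 to -0.67. The subtracted median was taken over 162 peaks, which hold the distal peaks of CROT (28), ABCB4 (25), ABCB1 (19) and RUNDC3B (14). These losses were thus partly fixed in advance and do not test the rise at ABCB1.

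**Figure D2:**
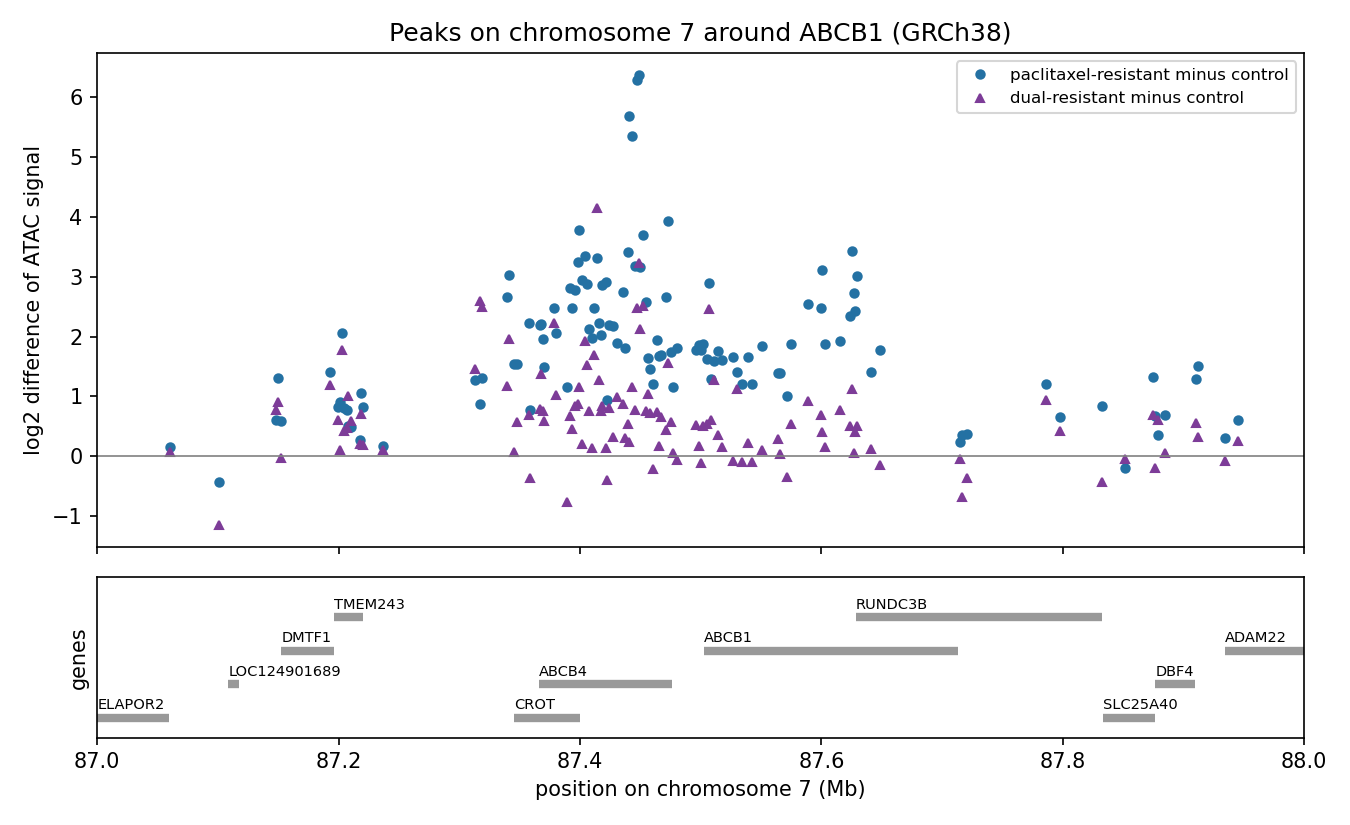
Log2 difference from control (y axis) of tested peaks on chromosome 7 by position in Mb on hg38 (x axis), with circles for paclitaxel-resistant and triangles for dual-resistant cells and gene spans drawn beneath. The peak inside ABCB4 lay at 6.36 in paclitaxel-resistant and 3.22 in dual-resistant cells, and the strongest ABCB1 peak at 2.43 and 0.41. That ABCB1 peak is also the gene-end peak of RUNDC3B.

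Outside this region, TUBB1, a beta-tubulin gene of platelets and their precursors, rose from 0.194 ± 0.0901 to 10.5 ± 0.748 CPM (20:59027471-59028471; 3.99, SE 0.48, adjusted p = 2.17e-11). ASIP, the agouti signalling gene, rose from 0.583 ± 0.278 to 28.8 ± 2.32 CPM (4.78, SE 0.39, adjusted p = 2.03e-19). LUM and DCN, genes of small proteoglycans of the extracellular matrix, rose to 25.8 ± 0.585 and 14.8 ± 0.346 CPM from 1.42 ± 0.173 and 0.515 ± 0.545 CPM. SLC7A11, which encodes the cystine transporter that feeds glutathione synthesis, fell from 34.4 ± 3.79 to 2.69 ± 0.312 CPM (4:138241807-138242807; -3.45, SE 0.18, adjusted p = 3.21e-32). NOX4 fell from 25.4 ± 0.175 to 0.818 ± 0.0447 CPM (11:89589775-89590775; -4.29, adjusted p = 2.04e-20). PI15, a peptidase inhibitor gene, fell from 29.5 ± 4.05 to 0.519 ± 0.219 CPM (8:74823518-74824518; -4.89), and 45 of its 57 distal peaks were lower.

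Over all protein-coding gene ends, 2032 of 15952 were higher and 1544 lower in this comparison. Interferon-stimulated genes had 17 of 38 lower and 5 higher (19 and 5 adjusted over the list alone; camera adjusted p = 0.000388, adjusted p = 0.155 with an estimated correlation). IFITM3, a gene of antiviral membrane proteins, fell from 25.3 ± 1.75 to 5.95 ± 0.00495 CPM (-2.00), IFIH1 to 4.79 ± 0.0965 CPM (-2.15) and MX1 from 14.6 ± 2.11 to 4.96 ± 2.21 CPM (-1.52). Stem cell associated genes had 7 of 22 lower and 1 higher (11 and 1 adjusted over the list alone; camera adjusted p = 0.00522, adjusted p = 0.155 with an estimated correlation). LIN28A was at 3.5 ± 0.0263 CPM (-2.58) and SOX9, a transcription factor gene, at -2.22. TGF-beta and BMP signalling had 10 of 28 lower and 1 higher (12 and 1 adjusted over the list alone; camera adjusted p = 0.00575, adjusted p = 0.158 with an estimated correlation). With median-ratio scaling the counts were 6 lower and 4 higher. The receptor gene TGFBR2 fell from 9.84 ± 1.71 to 1.80 ± 0.48 CPM (-2.18), and the ligand genes BMP4 (-1.73) and INHBA (-1.45) fell. Receptor tyrosine kinases and ligands had 13 of 41 lower and 4 higher, the same adjusted over the list alone (camera adjusted p = 0.00608, adjusted p = 0.158 with an estimated correlation). DUSP6, which encodes a phosphatase of ERK and is induced by its signalling, fell from 42.9 ± 1.76 to 5.13 ± 1.85 CPM (-2.99, SE 0.15, adjusted p = 4.63e-34), and PDGFRA from 30.9 ± 5.61 to 9.40 ± 0.266 CPM (-1.65).

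Mismatch repair had 4 of 10 genes higher and 0 lower (5 and 0 adjusted over the list alone; camera adjusted p = 0.00575, adjusted p = 0.155 with an estimated correlation). Median-ratio scaling gave 7 higher and 0 lower. Cytochrome P450 and aldo-keto genes had 3 of 13 lower and 1 higher, the same adjusted over the list alone (camera adjusted p = 0.0261, adjusted p = 0.158 with an estimated correlation). CYP1B1, a cytochrome P450 gene, fell from 43.3 ± 0.0249 to 14.1 ± 1.51 CPM (-1.59). Housekeeping controls, which served as a check, rose as well, with 5 of 18 higher and 0 lower under the CPM, quantile and loess scalings and 10 higher under the median-ratio scaling (6 and 0 adjusted over the list alone; camera adjusted p = 0.00843, adjusted p = 0.155 with an estimated correlation). After regional subtraction the housekeeping call was lost (adjusted p = 0.105). ACTB, the beta-actin gene, went from 17.9 ± 4.06 to 76.6 ± 2.28 CPM (2.08) and TBP, whose end is shared with PSMB1, from 28.9 ± 6.29 to 62.9 ± 2.94 CPM (1.12). NF-kB and inflammatory genes had 4 of 22 higher and 5 lower, and AP-1 and immediate early genes 4 of 23 higher and 6 lower, both the same adjusted over the list alone. Mesenchymal genes had 3 of 32 higher and 5 lower (3 and 7 adjusted over the list alone). With median-ratio scaling these counts turned to 5 higher and 4 lower for the NF-kB list, 5 and 2 for the AP-1 list and 5 and 4 for the mesenchymal list. The AP-1 median was 0.06 although its test pointed down. TRAF1, a signalling adaptor gene, was at 11.2 ± 1.44 CPM against 0.71 ± 0.269 CPM (3.29). Fibroblast markers had 3 of 13 higher and 3 lower, haematopoietic markers 3 of 16 higher and 1 lower, and endothelial markers 1 of 8 higher and 3 lower (3 and 4, 3 and 1, and 1 and 3 adjusted over the list alone). The fibroblast median was -0.21 although the mean was 0.25. Quantile and loess scaling gave 1 higher and 1 lower for the haematopoietic markers. Camera did not call the NF-kB, AP-1, mesenchymal, fibroblast, haematopoietic or endothelial list here (adjusted p = 0.146 to 0.968).

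Among the fixed genes, the strongest peak over CDKN1A, the p21 cell cycle inhibitor gene (6:36678453-36679453), rose from 19.3 ± 0.591 to 39.1 ± 0.34 CPM (1.0, SE 0.14, adjusted p = 4.59e-09). Its gene end was at 14.2 ± 2.36 CPM (0.76, adjusted p = 0.00545), a call lost without control library 1 (0.66) or paclitaxel-resistant library 2 (0.59) and after regional (0.37) or chromosome subtraction (0.29). The strongest ABCG2 peak fell to 11.1 ± 0.276 CPM (-0.81, adjusted p = 0.00108, with no call without control library 2, -0.68). ATP7B stood at 0.35 (adjusted p = 0.0123), a call lost without control library 2 (0.29), without paclitaxel-resistant library 1 (0.25) and with quantile (0.22) or loess scaling (0.23). The gene end (0.27, adjusted p = 0.251) and the strongest peak (-0.15, adjusted p = 0.537) of TUBB3, SLC31A1 (0.07, adjusted p = 0.711), GSTP1 (0.04, adjusted p = 0.905) and ALDH1A1 (0.80, adjusted p = 0.294) were not called. Over all peaks 26082 were called, 11525 higher and 14557 lower. The 44.2% share of higher peaks became 52.7% with quantile scaling, 61.4% with median-ratio scaling, 58.1% with loess scaling, 56.9% after regional and 58.2% after chromosome subtraction. Without control library 1 the calls were 9013 higher and 9162 lower, and without control library 2 they were 9056 higher and 8897 lower. The median over all peaks was -0.14 in this comparison, so differences are relative to a slightly lower centre. Peaks at gene ends were called in 18.6% (2618 higher, 2413 lower), inside genes in 14.1% (4014 higher, 5865 lower) and outside genes in 18.2% (4893 higher, 6279 lower). Distal peaks were mostly higher around SPTBN1 (81 of 119), EPHA3 (49 of 62) and HAPLN1 (47 of 57) and mostly lower around DLG1 (76 of 95), REEP3 (65 of 98) and PAX2 (58 of 80). After regional subtraction the higher distal peaks numbered 21 around SPTBN1, 7 around EPHA3 and 23 around HAPLN1, and the lower ones 25 around REEP3. EPHA3 itself rose by 1.80, a call lost after regional subtraction (0.22). The gene ends of SPTBN1 (0.22) and REEP3 (-0.06) were not called and stood at -0.58 and 0.84 after it.

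In dual-resistant cells against control, NOX4 had the largest fall among the named gene ends, from 25.4 ± 0.175 to 0.322 ± 0.456 CPM (log2 difference -5.09, SE 0.34, adjusted p = 8.16e-25). PI15 fell to 0.607 ± 0.509 CPM (-4.83, with 47 of 57 distal peaks lower) and SLC7A11 to 7.29 ± 0.884 CPM (-2.16). IFT70A, a gene of cilium transport, fell from 18.9 ± 3.25 to 0.293 ± 0.11 CPM (2:177618323-177619323; -4.61, SE 0.29, adjusted p = 4.83e-26). COL6A3, a collagen VI gene (2:237322110-237323110), rose from 1.43 ± 0.924 to 15.6 ± 0.161 CPM (3.15, SE 0.38, adjusted p = 6.09e-11), and 51 of its 60 distal peaks were higher. CDH7, a cadherin gene, rose from 0.714 to 21.6 ± 1.57 CPM (4.38), and CASP10, an initiator caspase gene, from 1.55 ± 0.538 to 9.59 ± 1.33 CPM (2.32).

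Over all protein-coding gene ends, 775 of 15952 were higher and 2360 lower in this comparison. List counts are again to be read beside this lean, and beside the smaller share of reads in the strongest peaks of these libraries. Mesenchymal genes had 8 of 32 higher and 3 lower (9 and 4 adjusted over the list alone; camera adjusted p = 0.00819, adjusted p = 0.226 with an estimated correlation). COL3A1 (1.83) and the cadherin gene CDH11 (2.05, 15 of 18 distal peaks higher) rose, while POSTN, the periostin gene, fell from 5.69 ± 0.144 to 0.516 ± 0.0302 CPM (-2.61). Interferon-stimulated genes had 16 of 38 lower and 1 higher (18 and 1 adjusted over the list alone; camera adjusted p = 0.00281, adjusted p = 0.226 with an estimated correlation). IFIT3 fell from 25.4 ± 2.28 to 4.74 ± 0.588 CPM (10:89327657-89328657; -2.31, SE 0.19, adjusted p = 2.45e-19), IRF1 from 53 to 21.2 ± 0.423 CPM (-1.30) and IFIH1 to 8.70 ± 0.292 CPM (-1.35), while PSMB8, an immunoproteasome gene, rose (1.0). Both list calls were lost after regional subtraction (adjusted p = 0.0639 for the mesenchymal and 0.0584 for the interferon list). Fibroblast markers had 4 of 13 higher and 3 lower, haematopoietic markers 3 of 16 higher and 0 lower, each the same adjusted over the list alone, and endothelial markers 1 of 8 higher and 2 lower (1 and 3 adjusted over the list alone). None of the 3 marker lists was called by camera (adjusted p = 0.128 to 0.661, 1 of them at an unadjusted p under 0.05).

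TGF-beta and BMP signalling had 9 of 28 lower and 0 higher (10 and 1 adjusted over the list alone), with TGFBR2 at 1.47 ± 0.505 CPM (-2.41, SE 0.28, adjusted p = 6.63e-12) and BMP4 at -1.65. AP-1 and immediate early genes had 7 of 23 lower and 0 higher (10 and 1 adjusted over the list alone), BATF3 among them (-1.22). Receptor tyrosine kinases and ligands had 10 of 41 lower and 2 higher (14 and 3 adjusted over the list alone). NF-kB and inflammatory genes had 8 of 22 lower and 2 higher, the same adjusted over the list alone, although TRAF1 rose to 11.8 ± 0.0533 CPM (3.36). Quantile and loess scaling gave 4 lower and 1 higher for the NF-kB list. Camera did not call these 4 lists, with adjusted p = 0.112 for TGF-beta, 0.244 for AP-1, 0.362 for receptor tyrosine kinase and 0.815 for NF-kB genes (the first 2 at an unadjusted p under 0.05). Stem cell associated genes had 5 of 22 lower and 0 higher (6 and 0) and mismatch repair 3 of 10 lower and 1 higher (4 and 1). Cytochrome P450 and aldo-keto genes had 4 of 13 lower and 1 higher (5 and 1) and neighbours of ABCB1 1 of 13 higher and 0 lower (1 and 0), with counts adjusted over the list alone in brackets in these 4 cases. Housekeeping controls had 1 higher and 1 lower of 18 (2 and 1 adjusted over the list alone), which became 3 and 0 with quantile and loess scaling and 1 and 3 with median-ratio scaling. The last 5 lists were not called by camera either (adjusted p = 0.298 to 0.852, 0 at an unadjusted p under 0.05).

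The strongest peak over ABCB1, at the RUNDC3B gene end, stood at 26.9 ± 1.56 CPM against 20.2 ± 0.14 CPM (0.41, adjusted p = 0.0231), a call lost without either control or either dual-resistant library (0.35 to 0.47), and -0.057 after regional subtraction. The peak inside ABCB4 described above was at 12.6 ± 1.57 CPM (3.22, adjusted p = 2.79e-22). The strongest ABCG2 peak fell to 7.94 ± 1.19 CPM (-1.28, SE 0.20, adjusted p = 1.67e-07). The strongest TUBB3 peak fell to 20.7 ± 1.88 CPM (-0.44, adjusted p = 0.0283), a call lost without control library 1 (-0.26), without either dual-resistant library (-0.35 and -0.53), with quantile (-0.34) or loess scaling (-0.35) and after regional subtraction (-0.38). The CDKN1A gene end stood at 12.5 ± 2.05 against 8.15 ± 0.858 CPM (0.59, adjusted p = 0.0495), a call lost in 15 settings, among them each control and dual-resistant library left out (0.42 to 0.75). The TUBB3 gene end (0.10, adjusted p = 0.759) and the strongest CDKN1A peak (0.15, adjusted p = 0.564) were not called. In all 21425 peaks were called, 12864 higher and 8561 lower. The 60.0% share of higher peaks became 49.9% with median-ratio scaling, 44.5% after regional and 47.4% after chromosome subtraction. Without control library 1 the count was 14054 (8901 higher, 5153 lower) and without dual-resistant library 1 it was 12033 (6684 higher, 5349 lower). Without control library 2 the lower count was 5465, and without dual-resistant library 2 the higher count was 7886. Peaks at gene ends were called in 14.9% (1420 higher, 2628 lower), inside genes in 11.1% (5066 higher, 2734 lower) and outside genes in 15.6% (6378 higher, 3199 lower). Distal peaks were mostly higher around SPTBN1 (115 of 119), SIPA1L2 (80 of 103) and COL6A3 and mostly lower around PI15, FERMT2 (44 of 60) and SPRED1 (44 of 68). After regional subtraction 13 were higher around SPTBN1 and 36 around SIPA1L2. The SPTBN1 gene end was not called (0.05) and stood at -1.48 after it.

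The resistant lines were then compared with each other. Dual-resistant cells had far less signal at PI15 than cisplatin-resistant cells (0.607 ± 0.509 against 56.5 ± 1.69 CPM; log2 difference -5.76, SE 0.27, adjusted p = 1.55e-36). The same held at LY6K (0.715 ± 0.661 against 29.0 ± 0.19 CPM; -4.72). They had more at NTS, the neurotensin gene (12:85873784-85874784; 41.8 ± 0.00967 against 0.68 ± 0.63 CPM; 5.28, SE 0.25, adjusted p = 1.59e-35), and at the gene end of CDKN1A (12.5 ± 2.05 against 5.73 CPM; 1.06, adjusted p = 1.91e-05). The TUBB3 gene end was lower (-0.57, adjusted p = 0.00189), and its strongest peak was not called (0.04, adjusted p = 0.841). The strongest ABCB1 peak, at the RUNDC3B gene end, differed by 0.44 (adjusted p = 0.00408). That call was lost without cisplatin-resistant library 1 (0.10) or dual-resistant library 2 (0.38), with median-ratio scaling (0.25) and after regional (0.09) or chromosome subtraction (0.22), and the value was 0.78 without cisplatin-resistant library 2. The test called 66334 peaks, 34800 higher and 31534 lower in dual-resistant cells, and the share of higher peaks went from 52.5% to 40.1% with median-ratio scaling, 47.8% with loess scaling, 39.8% after regional and 41.3% after chromosome subtraction. It was 48.0% without dual-resistant library 1 and 48.9% without dual-resistant library 2.

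Against paclitaxel-resistant cells, dual-resistant cells had less signal at the strongest ABCB1 peak (-2.02, SE 0.13, adjusted p = 2.42e-25), at TUBB1 (0.231 ± 0.0229 against 10.5 ± 0.748 CPM; -3.91), at LUM (1.58 ± 0.563 against 25.8 ± 0.585 CPM; -3.69) and at the strongest CDKN1A peak (-0.85, adjusted p = 5.4e-07). IFI16, a gene of a nuclear DNA sensor whose end is shared with PYDC5, was higher (1:158999532-159000532; 25.2 ± 1.93 against 1.04 ± 0.438 CPM; 4.09, SE 0.30, adjusted p = 4.05e-22). So was the pigment gene TYRP1 (14.5 ± 0.193 against 0.178 ± 0.0922 CPM; 4.47). The test called 35484 peaks, 23681 higher and 11803 lower, with 23586 called without paclitaxel-resistant library 1, 20824 without dual-resistant library 1 and 23358 without dual-resistant library 2. The 66.7% share of higher peaks became 50.5%, 42.1% and 47.7% with quantile, median-ratio and loess scaling, 41.1% after regional and 41.9% after chromosome subtraction. The median over all peaks was 0.23 in this comparison and 0.16 between dual-resistant and cisplatin-resistant cells.

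Paclitaxel-resistant cells had more signal than cisplatin-resistant cells at the strongest ABCB1 peak (111 against 20.3 ± 6.87 CPM; 2.46, adjusted p = 5.16e-32) and at HAPLN1, a gene of a matrix link protein (49.2 ± 1.69 against 1.89 ± 0.517 CPM; 4.40, SE 0.18, adjusted p = 2.12e-40). They also had more at NTS (31.9 ± 3.15 CPM; 4.89). They had less at PI15 (-5.82) and at CCL20 (0.355 ± 0.184 against 24.3 CPM; -4.88). The test called 61483 peaks, 24272 higher and 37211 lower, and the 39.5% share of higher peaks became 51.3% with quantile scaling. By camera, 1 list was called between dual- and cisplatin-resistant cells, 2 between dual- and paclitaxel-resistant cells and 5 between paclitaxel- and cisplatin-resistant cells, and 0 with an estimated correlation.

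The overlap of the comparisons with control was counted next. Paclitaxel- and dual-resistant cells shared 7818 peaks called in the same direction (3727 higher, 4091 lower) and 898 called in opposite directions, where independent lists would share 934 higher and 785 lower. Cisplatin- and paclitaxel-resistant cells shared 8103 (2276 higher, 5827 lower) with 2801 opposite, against 2113 and 2171 for independent lists. Cisplatin- and dual-resistant cells shared 6451 (2570 higher, 3881 lower) with 2045 opposite, against 2358 and 1277. Simulated unchanged groups that shared simulated control libraries had at most 2 peaks in common in any of 20 runs. Without any true change few peaks can be called, so this count cannot gauge what shared controls add to the overlaps above. Across peaks, log2 differences correlated at 0.45 for paclitaxel with dual, 0.18 for cisplatin with paclitaxel and 0.13 for cisplatin with dual, beside 0.50 in simulated unchanged groups. The covariances were 0.272, 0.157 and 0.101 beside a simulated 0.0692, which leaves 0.203, 0.0883 and 0.0316. The controls were not split, since each part would keep 1 library, so part of the overlap beyond independent lists may come from the shared controls.

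Median signal over 5 Mb bins was shifted in each resistant line. A bin median need not hold for every peak in the bin, and the SPTBN1 gene end, not called above, did not follow its bin. Of 595 bins of 5 Mb, 77 were shifted in cisplatin-resistant cells (43 higher, 34 lower), 49 in paclitaxel-resistant cells (27 higher, 22 lower) and 41 in dual-resistant cells (36 higher, 5 lower). With a threshold of 0.3 the balance turned to 94 higher and 110 lower in cisplatin-resistant and 59 higher and 87 lower in paclitaxel-resistant cells. In cisplatin-resistant cells the bin from 130000001 to 135000000 on chromosome 6 had a median log2 difference of 1.69 over 148 peaks, and the bin that holds MYC on chromosome 8 had 1.20. In paclitaxel-resistant cells the bin that holds EPHA3 on chromosome 3 had 1.58 over 252 peaks, and the bin that holds ABCB1 on chromosome 7 had 1.34 over 162 peaks, beside 0.46 in dual-resistant and 0.12 in cisplatin-resistant cells. In dual-resistant cells a bin of chromosome 16 had 2.12 over 77 peaks, and the bin that holds SPTBN1 on chromosome 2 had 1.53 over 290 peaks, beside 0.80 in paclitaxel-resistant cells. One bin was shifted in all 3 lines, from 215000001 to 220000000 on chromosome 1 with 229 peaks, which holds ESRRG (-0.93, -1.06 and -1.03 in cisplatin-, paclitaxel- and dual-resistant cells). By whole chromosome and relative to all peaks, paclitaxel-resistant cells were higher on chromosomes 6 (0.59) and 7 (0.46), and cisplatin-resistant cells higher on chromosome 8 (0.42) and lower on chromosome 18 (-0.24).

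**Figure D3:**
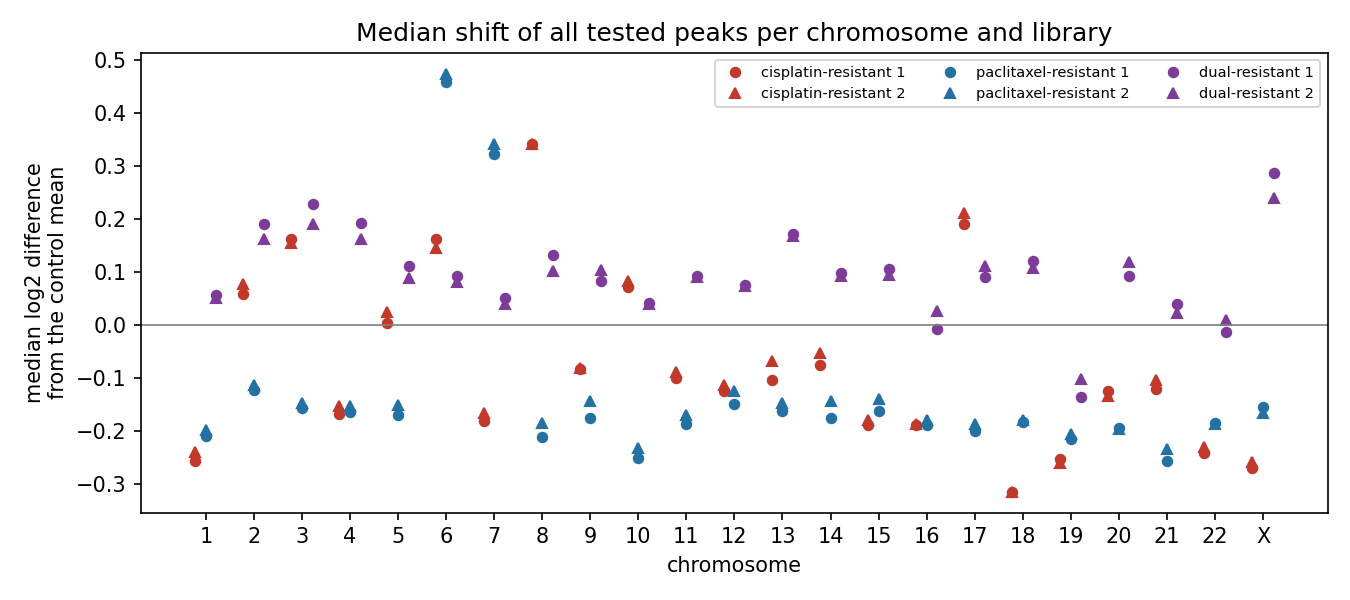
Median log2 difference from the control mean (y axis) of tested peaks on each chromosome (x axis), with 1 point for each of the 6 resistant libraries. Paclitaxel-resistant libraries lay at 0.458 and 0.474 on chromosome 6, cisplatin-resistant libraries at 0.342 and 0.342 on chromosome 8, and the libraries of a line lay close together.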

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

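Of the tests reported in this part, those of the ABCB1 pattern and the search for empty runs of peaks were chosen after the result was seen, and the other 2 tests of the cisplatin-resistant libraries before it.

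A test of the difference between groups picked out 54425 peaks at which the dual-resistant line departed from the sum of the log2 differences of the single-resistant lines (limma, Benjamini-Hochberg adjusted), 30672 of them above that sum and 23753 below. The 56.4% share above the sum became 36.3% with median-ratio scaling, 44.3% with loess scaling, 37.2% after regional and 38.3% after chromosome subtraction, and the median over all peaks was 0.22. Among the fixed genes, the strongest peak over ABCB1, which is also the gene-end peak of RUNDC3B, departed by -1.99 (SE 0.19, adjusted p = 4.24e-16). The gene end of ABCB1 itself departed by -1.82 (SE 0.58, adjusted p = 0.0102). The strongest CDKN1A peak departed by -1.02 (adjusted p = 1.99e-05), the TUBB3 gene end by -0.84 (adjusted p = 0.00169) and the strongest ABCG2 peak by 0.72 (adjusted p = 0.0354).

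Signal in the names of the peaks, which no comparison used, differed from control. The highest peak number in a name was at least 70011 in cisplatin-resistant, 51464 in paclitaxel-resistant and 70820 in dual-resistant libraries, against 9593 and 9965 in the control libraries, at 7.11 times the peak number and 1.04 times the reads between a dual-resistant and a control library. Of peaks with a group mean of at least 5 CPM that were at least 2-fold highest in control, 26.1% of 559 carried a control name, while 99.7% of 10381 in cisplatin-resistant, 99.3% of 2044 in paclitaxel-resistant and 99.7% of 1878 in dual-resistant cells carried the name of their own line. Counts of lower peaks against control therefore rest on a peak set with few control names.

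The first pattern weighed was how far the cisplatin-resistant libraries lay from control. A difference in reads in peaks was argued against by the depths, which were 8885297 and 8552256 in cisplatin- and 8236447 and 8898337 in paclitaxel-resistant libraries. At such like depths, thinning every library to the reads of the shallowest could change little and adds no support of its own. After it the correlation with control was 0.806 for paclitaxel-resistant and 0.663 for cisplatin-resistant libraries, a gap of 0.143. Regional shifts were argued against as the whole cause, because after their subtraction 2.02 times as many peaks were called in cisplatin- as in paclitaxel-resistant cells. Cells of another origin under the cisplatin-resistant name cannot be told apart from a wide change of chromatin, since the number of runs of at least 5 peaks empty in control but present in cisplatin-resistant cells was 0, which excludes neither. Cisplatin resistance itself, the difference the design names, may account for the distance and was not tested separately. The labels name a single line for each resistance state, so resistance cannot be told apart from other differences between the lines.

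The second pattern was the raised signal around ABCB1 in paclitaxel-resistant cells. A gain of the whole of chromosome 7 was argued against as the whole cause. The median over the 28 peaks of ABCB1 was 1.77 and that over 9495 peaks of the chromosome outside ABCB1 and its listed neighbours 0.31. The difference was 1.46, or 1.26 among peaks named after a paclitaxel-resistant library. The chromosome itself stood 0.46 higher relative to all peaks in paclitaxel-resistant cells, so such a gain as part of the rise was not excluded. Whether extra copies of a short segment contributed cannot be told apart from opening of chromatin, since the number of weak ABCB1 peaks (under 1.5 CPM in cisplatin- and dual-resistant cells) named after a library of another line was 0, which leaves no weak peak chosen without regard to paclitaxel-resistant signal. Extra copies as the whole cause would raise these peaks by like amounts. The 20 called peaks of ABCB1 and ABCB4 with at least 1 CPM in control spanned log2 differences from 1.20 to 3.43. That gap of 2.23, beside a largest SE of 0.44, cannot decide the question. A range over 20 estimates exceeds the SE of a single peak by noise alone, and the log2 scale understates the rise of weak peaks. Paclitaxel resistance itself, the difference the design names, may account for the rise and was not tested separately. With a single paclitaxel-resistant line, it cannot be told apart from other differences of that line.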

How the results depend on the processing

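Of the tests in this part, the edgeR fit, the chromosome medians, the fit without the cisplatin-resistant group, the distal peak counts after regional subtraction and the strongest-peak list tests were chosen after the result was seen. Over 366 named results and 8242 values under other settings, 7954 kept their side of the threshold, 216 lost a call, 66 gained one and 6 reversed. A change of sign counted as a reversal only where the result was called under the main or the other setting. Results called under neither that changed sign are among the 7954. The 6 reversals came after regional medians were subtracted, which by construction removes the shift of a region, for the gene ends of MYC in cisplatin-resistant (-0.15), DLG1 in cisplatin-resistant (0.26), SPTBN1 in paclitaxel-resistant (-0.58) and dual-resistant (-1.48), REEP3 in paclitaxel-resistant (0.84) and the strongest ABCB1 peak in dual-resistant cells (-0.057). The median of the neighbours of ABCB1 in paclitaxel-resistant cells reversed likewise to -0.67. Leaving out 1 library, with the lone library assumed to vary like the other groups, gave 12033 to 21507 calls for dual-resistant against control and 20824 to 35632 against paclitaxel-resistant cells, and the lower calls of the paclitaxel comparison with control went from 14557 to 8897 without control library 2. Quantile scaling moved the median over all peaks of the cisplatin comparison from -0.09 to -0.19 and that of paclitaxel- against cisplatin-resistant cells from -0.06 to 0.14. Calls by edgeR on recovered reads were 50353 in cisplatin-, 25003 in paclitaxel- and 20664 in dual-resistant cells. Calls by limma without the cisplatin-resistant group were 26199 in paclitaxel- and 21669 in dual-resistant cells.

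With an estimated correlation 0 lists were called in paclitaxel- and 0 in dual-resistant cells. With the mean of all gene-end peaks 2 lists were called in cisplatin- and 1 in dual-resistant cells, and after regional subtraction 2 and 0. The strongest peak over each gene gave 0, 8 and 3 lists. The cause was not tested. With a log2 minimum of 1, cisplatin-resistant cells shared 4469 calls of the same direction with paclitaxel- and 3351 with dual-resistant cells, and opposite calls were 1432, 1076 and 423 for cisplatin with paclitaxel, cisplatin with dual and paclitaxel with dual, as fewer peaks pass a stricter threshold. Bins of 10 Mb, of which there are fewer, gave 25, 18 and 11 shifted bins in cisplatin-, paclitaxel- and dual-resistant cells, and a lower threshold of 0.3 gave 204, 146 and 110. Libraries that share a number had deviations correlated at -0.000587 to 0.00332, so the numbers did not pair them. With the replicate number as a block, 52998, 26376 and 21678 peaks were called against control, and no call of a named gene or list changed. Depth limited the weakest peaks, where 1 read was worth 0.107 to 0.130 CPM, and the planned motif tests were not run.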

Other observations

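No test in this part offers an explanation, and the gene lists described here were fixed in advance and tested with the others. HOX genes, which pattern the body axis, had 15 of 35 lower and 2 higher in cisplatin-resistant cells, 4 lower and 2 higher in paclitaxel-resistant cells and 13 lower and 3 higher in dual-resistant cells (15 and 2, 7 and 2, and 13 and 3 adjusted over the list alone). With median-ratio scaling the HOX counts in paclitaxel-resistant cells turned to 1 lower and 2 higher, while after regional subtraction camera called the list down there (adjusted p = 0.00397, against 0.189 without it, and adjusted p = 0.360 with an estimated correlation and no subtraction). WNT signalling had 8 of 38 lower and 6 higher in cisplatin-resistant, 8 lower and 4 higher in paclitaxel-resistant and 7 lower and 0 higher in dual-resistant cells (9 and 6, 10 and 6, and 9 and 2 adjusted over the list alone). The ligand gene WNT3A rose in cisplatin-resistant cells from 5.24 ± 0.311 to 23.6 ± 1.47 CPM (2.07), and the receptor gene FZD8 fell in dual-resistant cells from 21.3 to 9.40 CPM (-1.14). With median-ratio scaling WNT counts in paclitaxel-resistant cells turned to 7 higher and 6 lower, and with loess scaling those in cisplatin-resistant cells to 6 higher and 5 lower, and median-ratio scaling gave 11 lower and 0 higher in dual-resistant cells. NOTCH signalling had 5 of 23 lower and 0 higher, 3 lower and 4 higher, and 6 lower and 1 higher in cisplatin-, paclitaxel- and dual-resistant cells (4 and 0, 3 and 5, and 6 and 1 adjusted over the list alone), and loess scaling gave 1 lower and 2 higher in the first and 3 lower and 3 higher in the second. Epithelial genes had 9 of 28 lower and 5 higher, 5 lower and 2 higher, and 4 lower and 1 higher in the same order (9 and 5, 5 and 2, and 5 and 1 adjusted over the list alone), and loess scaling gave 4 lower and 4 higher in the first, with the tight junction gene OCLN down in dual-resistant cells from 28.6 to 10.7 ± 2.03 CPM (-1.39).

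Glutathione, metallothionein and NRF2 targets had 5 of 35 higher and 10 lower in cisplatin-resistant, 5 higher and 2 lower in paclitaxel-resistant and 2 higher and 3 lower in dual-resistant cells, the same adjusted over the list alone, and loess scaling turned the first to 9 higher and 4 lower. Median-ratio scaling gave 11 higher and 1 lower in paclitaxel-resistant cells, and quantile or loess scaling 1 and 1 in dual-resistant cells. In cisplatin-resistant cells GSTM3, a glutathione transferase gene, rose from 0.904 ± 0.543 to 7.44 ± 1.26 CPM (2.55), TXNRD1, a thioredoxin reductase gene, from 0.838 ± 0.817 to 5.79 ± 0.411 CPM (2.38) and the metallothionein gene MT1E from 3.10 ± 1.62 to 11.8 ± 1.71 CPM (1.85). Reads of GSTM3 and MT1E can be shared with near copies. In paclitaxel-resistant cells ME1, the malic enzyme gene, rose from 7.76 to 31.5 ± 2.63 CPM (1.95). Nucleotide excision, crosslink and homologous repair had 8 of 44 higher and 9 lower, 11 higher and 1 lower, and 1 higher and 10 lower in cisplatin-, paclitaxel- and dual-resistant cells (8 and 11, 12 and 1, and 1 and 10 adjusted over the list alone). Loess scaling turned the repair counts to 13 higher and 4 lower in cisplatin-resistant cells, and quantile scaling to 4 higher and 3 lower in dual-resistant cells. In paclitaxel-resistant cells they were 6 higher and 3 lower with quantile or loess and 21 and 0 with median-ratio scaling. Drug efflux and uptake transporters had 2 of 22 higher and 6 lower, 4 higher and 5 lower, and 0 higher and 3 lower (2 and 6, 4 and 5, and 1 and 4 adjusted over the list alone), with 5 higher and 1 lower in paclitaxel-resistant cells under median-ratio and 2 higher and 3 lower in cisplatin-resistant cells under loess scaling. Tubulins and microtubule regulators had 5 of 39 higher and 7 lower, 7 higher and 1 lower, and 1 higher and 7 lower (5 and 4, 7 and 1, and 1 and 10 adjusted over the list alone), and quantile scaling turned the first to 7 higher and 5 lower. In dual-resistant cells the tubulin counts were 1 higher and 2 lower with quantile, 1 and 1 with loess and 1 and 14 with median-ratio scaling, and median-ratio scaling gave 11 higher and 0 lower in paclitaxel-resistant cells. Mismatch repair in cisplatin-resistant cells had 2 of 10 higher and 2 lower, the same adjusted over the list alone, which became 3 and 1 under each other scaling.

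Cell fate lists went both ways. The p53 targets had 7 of 24 higher and 6 lower, 4 higher and 4 lower, and 2 higher and 7 lower in cisplatin-, paclitaxel- and dual-resistant cells (7 and 7, 4 and 4, and 2 and 7 adjusted over the list alone), and quantile scaling gave 3 higher and 2 lower in the last, while median-ratio scaling gave 9 higher and 2 lower in paclitaxel-resistant cells. Apoptosis regulators had 4 of 30 higher and 8 lower, 3 higher and 3 lower, and 1 higher and 6 lower (4 and 8, 3 and 3, and 1 and 9 adjusted over the list alone), with 5 higher and 2 lower in cisplatin-resistant cells under loess and 6 higher and 3 lower in paclitaxel-resistant and 1 higher and 10 lower in dual-resistant cells under median-ratio scaling. CASP10 rose in paclitaxel-resistant cells to 12.2 ± 1.82 CPM from 1.55 CPM (2.65). Cell cycle genes had 2 of 32 higher and 8 lower, 6 higher and 3 lower, and 2 higher and 4 lower, the same adjusted over the list alone, and turned to 5 higher and 1 lower in cisplatin-resistant and 2 higher and 1 lower in dual-resistant cells under loess scaling, which gave 3 higher and 2 lower in paclitaxel-resistant cells. Cancer-testis antigens had 2 of 10 higher and 1 lower, 0 and 0, and 1 higher and 0 lower (3 and 1, 0 and 0, and 2 and 0 adjusted over the list alone). In cisplatin-resistant cells housekeeping controls had 2 of 18 higher and 9 lower, neighbours of ABCB1 3 of 13 higher and 0 lower, and cytochrome P450 and aldo-keto genes 1 of 13 higher and 4 lower, each the same adjusted over the list alone. Loess scaling gave 2 higher and 3 lower for the housekeeping controls and 5 higher and 0 lower for the neighbours of ABCB1. Mismatch repair, housekeeping controls, neighbours of ABCB1 and cytochrome P450 and aldo-keto genes were called by camera in paclitaxel-resistant cells, and not with an estimated correlation (adjusted p = 0.155 for the first 3 and adjusted p = 0.158 for the last). None of the other lists in this part was called against control by camera on the deposited scale, and the smallest adjusted p among them in paclitaxel-resistant cells was 0.115, for the repair list.

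At SRI, the sorcin gene near ABCB1 (7:88226664-88227664), signal rose in cisplatin-resistant cells from 0.648 ± 0.37 to 11.1 ± 0.95 CPM (3.38, SE 0.43, adjusted p = 2.95e-10). A run of 5 peaks within DMD, the dystrophin gene (X:32403907-32484281, 80.4 kb), held 0 and 0 reads in the cisplatin-resistant libraries, 48 and 24 in control, 116 and 130 in paclitaxel-resistant and 51 and 29 in dual-resistant libraries.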
